A study of Agropyron mongolicum with 3 samples.

How the data were processed

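RNA was measured in 3 libraries of Agropyron mongolicum, a perennial wheatgrass. Per the labels' protocols, a single plant was divided into 3 equal parts, kept as a control or put under drought stress for 5 or 15 days, and each library was made from all tissues, among which root, leaf, stem and tassel are named. The RNA was DNase-treated, enriched by poly(A) capture or by rRNA removal, fragmented and sequenced with Illumina HiSeq protocols. The labels do not say which of the enrichment steps was used for which library. There was 1 library per group, and the groups were taken from the stress label of each sample.

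The authors deposited, per the file headers, a raw fragment count and an FPKM value (fragments scaled to transcript length and library total) for each of 92752 assembled transcripts, together with transcript length and first database hits (Nr, Nt and Swiss-Prot proteins or nucleotides, with E-values, and COG, KEGG and GO terms). The assembler, aligner, counter and database releases are not given in the sources used here. The deposited FPKM values were recomputed from the deposited counts, lengths and column totals, and the largest difference was 5.0e-05. The totals were 19093035 fragments in the control library, 17347277 at 5 days and 18323882 at 15 days. For a transcript of 1 kb, 3 fragments, the number used as the floor for a count of 0, correspond to 0.157, 0.173 and 0.164 FPKM.

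Ratios between libraries were computed from the deposited FPKM as log2 of FPKM plus a pseudocount of 1, which understates the ratio of transcripts at low levels. A transcript was counted as different when this ratio was at least 1 in size, that is 2-fold, and its level was at least 5 FPKM in the higher of the 2 libraries. Folds printed for single transcripts are ratios of the FPKM values themselves, with an exact 95% interval from the conditional binomial distribution of the raw fragment counts. Where a count was 0, the fold was computed against the floor of 3 fragments and is given as at least that value. Intervals and floors cover counting error only. With 1 library per group, no spread between plants or libraries could be estimated, no p-value was computed, and none of the differences has a replicate check.

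Before the data were examined, 47 gene lists were written as patterns on the annotation descriptions, among them markers of root, anther and pollen, and seed and spike, and lists for other organisms. Members were transcripts of at least 5 FPKM in the highest of the 3 libraries whose Swiss-Prot or Nr description matched. For the 43 lists with at least 5 members, the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from the 28421 annotated transcripts of at least 5 FPKM and matched in 20 bins of mean log2 level over the 3 libraries. A list is called above or below the random range when its median lay over the 97.5 or under the 2.5 percentile. These percentiles describe these libraries only. The lists for fungi, insects and mites, and bacteria, written as species names, matched 0 first protein hits and so say nothing about such organisms, and the list for proline and branched amino acid breakdown had 3.

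Transcripts are named by a rule fixed at the same time. For each drought library against the control, these are the 8 highest and 8 lowest ratios among informatively annotated transcripts of at least 20 FPKM in the higher library, one per description, and for the 15-day against the 5-day library the 4 highest and 4 lowest. To these were added the highest and lowest member of each list among members of at least 20 FPKM, and the 5 most abundant transcripts of each library. Descriptions are the first Swiss-Prot hit, or the Nr hit where there was none. They name a similar protein, not an established gene of this species, and several transcripts can come from copies of the same gene, between which the counting could have split fragments.

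TMM factors from edgeR 4.0.16 under R 4.3.3 and the upper quartile were used as alternative scalings. Other alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, other minimum levels, a 4-fold threshold, intervals beyond 2-fold, sums over shared descriptions, longer transcripts and unmatched random lists. A restriction to transcripts whose first nucleotide hit names a species of the grass subfamily Pooideae (wheat, barley, Brachypodium and relatives), for the counts, the lists and the overlap, totals without the seed and spike list, the upper quartile for the lists, a stricter E-value and, for the overlap, a level taken from the highest of the 3 libraries or from the control were added after seeing the data. The calls were tested on simulated data: with 92752 transcripts, Poisson counts at the real mean levels and 200 seeded changes, 98.5% of 3-fold and 100.0% of 4-fold changes were recovered for 5 days against control, 92.4% and 94.4% for 15 days, and 98.6% and 96.9% for 15 against 5 days. Of the unchanged transcripts 30 of 24386, 31 of 24383 and 46 of 24525 were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.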

Results

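Transcript levels were compared between 3 libraries of Agropyron mongolicum made from parts of a single plant, a control and parts under drought stress for 5 and 15 days, to describe the drought response of this grass. Each library was labelled as whole plant, with root, leaf, stem and tassel named, so a difference can lie in the level within a tissue or in the share of a tissue. The libraries held 19.09 M fragments (control), 17.35 M (5 days) and 18.32 M (15 days) on 92752 assembled transcripts. A fragment was counted on 79775, 86212 and 86394 of them, and 19580, 24533 and 25450 reached 5 FPKM. There was 1 library per group, so none of the differences below has a replicate check, and intervals in brackets are 95% counting intervals. The most abundant transcript of all 3 libraries encoded the large chain of Rubisco, the carbon-fixing enzyme (Unigene28198_All), at 24914 FPKM in the control, 34673 at 5 days and 19138 at 15 days.

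After 5 days of drought, the median ratio to the control library lay above that of matched random lists for dehydrins, protease inhibitors and the NAC and WRKY transcription factors, and below it for light reactions, aquaporins, cell wall loosening, wax synthesis and histones. The highest ratios belonged to seed storage proteins. A low molecular weight glutenin (Unigene5478_All) stood at 3.09 FPKM in the control and 17637 at 5 days, 5710-fold higher [3805 to 9008]. A second glutenin (CL5210.Contig1_All) was 6963-fold higher [4349 to 11954], and avenin-like a5 (CL6251.Contig1_All) 3082-fold higher [1676 to 6428]. Of 175 seed and spike markers 99 were at least 2-fold higher and 5 lower, and the list took 0.200% of control fragments and 3.70% at 5 days. At 15 days it took 0.306%. Trypsin inhibitor CMe and the vacuolar aquaporin TIP3-1, named below with their lists, had the same order of libraries as these markers, highest at 5 days and lowest in the control. At the other end, a germin-like protein (CL3838.Contig4_All) was 3108-fold lower at 5 days [860 to 25674], and a GDSL esterase/lipase (CL4656.Contig2_All), at 345 FPKM in the control, had no fragment at 5 days and was at least 562-fold lower.

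Of 43 lists, 14 lay above and 13 below the random range at 5 days, and 13 and 18 at 15 days, against 2.1 outside by construction. The 2.1 holds for lists of independently drawn transcripts, whereas members of these lists can be copies of the same gene and change together. Among genes tied to water deficit, 60 of 114 transcripts of LEA proteins and dehydrins, which protect dehydrating cells, were at least 2-fold higher at 5 days and 7 lower. Their median log2 ratio was 1.35, against 0.13 in matched random lists. Dehydrin DHN4 (CL50.Contig18_All) was 464-fold higher [286 to 812], while the cold-regulated protein BLT14 (Unigene1135_All) was 5.31-fold lower [4.47 to 6.34]. Compatible solute synthesis was also above the random range, with 11 of 26 members higher and 3 lower (7 and 6 after TMM rescaling), but lay within it under 7 of 11 alternatives, upper-quartile rescaling, a minimum of 20 FPKM and a first nucleotide hit in Pooideae, the grass subfamily of this species, among them. Water channels went the other way. Of 45 aquaporin transcripts 26 were lower and 7 higher, with a median log2 ratio of -1.26. NIP1-1 (Unigene2092_All) was 41.0-fold lower [27.4 to 64.3], and TIP3-1 (Unigene2577_All), with 1 control fragment, was 2800-fold higher [503 to 110725].

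Several lists of regulators and defence genes lay above the random range at 5 days. Of 87 WRKY transcripts 41 were higher and 0 lower, and WRKY 26 (Unigene19537_All) was 7.46-fold higher [6.65 to 8.40]. Of 74 NAC transcripts 36 were higher and 4 lower. AP2/ERF and DREB factors had 52 of 120 members higher and 15 lower; ERF110 (Unigene25374_All) was 38.0-fold higher [29.7 to 49.3] and DREB 1A (Unigene46479_All) 99.9-fold lower [27.3 to 830]. The ethylene synthesis list, which by its description match took in an oxidase homolog (Unigene576_All), was higher in 11 of 20 members and lower in 2. Protease and amylase inhibitors were higher in 31 of 56 and lower in 6, with trypsin inhibitor CMe (Unigene2596_All) at 0.155 FPKM in the control, 1001 at 5 days and 2.34 at 15 days. Glutathione S-transferases were higher in 33 of 84 members and lower in 14, while their summed level was 3250 FPKM in the control and 2934 at 5 days. Chlorophyll breakdown and senescence genes were higher in 8 of 18 and lower in 5. Retrotransposon transcripts were higher in 75 of 207 and lower in 5. A list meant for viruses was also above the range, but its members included retrotransposon polyproteins and plant proteins such as a coatomer subunit (Unigene28208_All), so it says nothing about viruses. Ubiquitin and proteasome transcripts lay above the random range with a median log2 ratio of 0.32, which became -0.03 after TMM rescaling while the list stayed above the range.

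Lists of photosynthesis and growth genes lay below the random range at 5 days. Of 89 light-reaction transcripts 66 were lower and 3 higher, with a median log2 ratio of -1.51. A chlorophyll a-b binding protein (Unigene57333_All) was 106-fold lower [67.9 to 177]. An exception was a photosystem II 10 kDa polypeptide (Unigene1571_All), at 1638 FPKM in the control and 13344 at 5 days, 8.15-fold higher [8.03 to 8.27]. Calvin cycle transcripts were lower in 16 of 32 members and higher in 0, and a Rubisco small chain (CL4416.Contig3_All) was 5.63-fold lower [5.53 to 5.73]. Chlorophyll synthesis was lower in 7 of 20 and higher in 1. Cell wall genes were lower in 90 of 164 members and higher in 15, among the lower a xyloglucan endotransglucosylase (Unigene57418_All), 376-fold lower [210 to 754]. Wax and cutin genes were lower in 27 of 43 and higher in 3, and lipid transfer proteins lower in 23 of 54 and higher in 10. Class III peroxidases were lower in 59 of 122 and higher in 37, with 35 lower and 32 higher among the 81 with a Pooideae hit and 24 lower and 5 higher among the 41 others. In the sucrose and fructan list, 32 of 94 were lower and 23 higher; a fructosyltransferase (CL9648.Contig1_All) was 25.3-fold lower [21.3 to 30.2] and a fructan exohydrolase (CL2030.Contig7_All), which breaks fructan down, 28.6-fold higher [22.7 to 36.5]. Histones, made mainly in dividing cells, were lower in 88 of 132 members with a median log2 ratio of -3.61; with a Pooideae hit 70 of 79 were lower and 1 higher, and of the 53 others 18 and 24. Cell cycle genes were lower in 74 of 151 and higher in 12. Tubulins and actins were lower in 29 of 96 and higher in 25, and the lower ones were among the 67 with a Pooideae hit (29 lower, 3 higher), while of the 29 others 22 were higher and 0 lower.

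**Figure D1:**
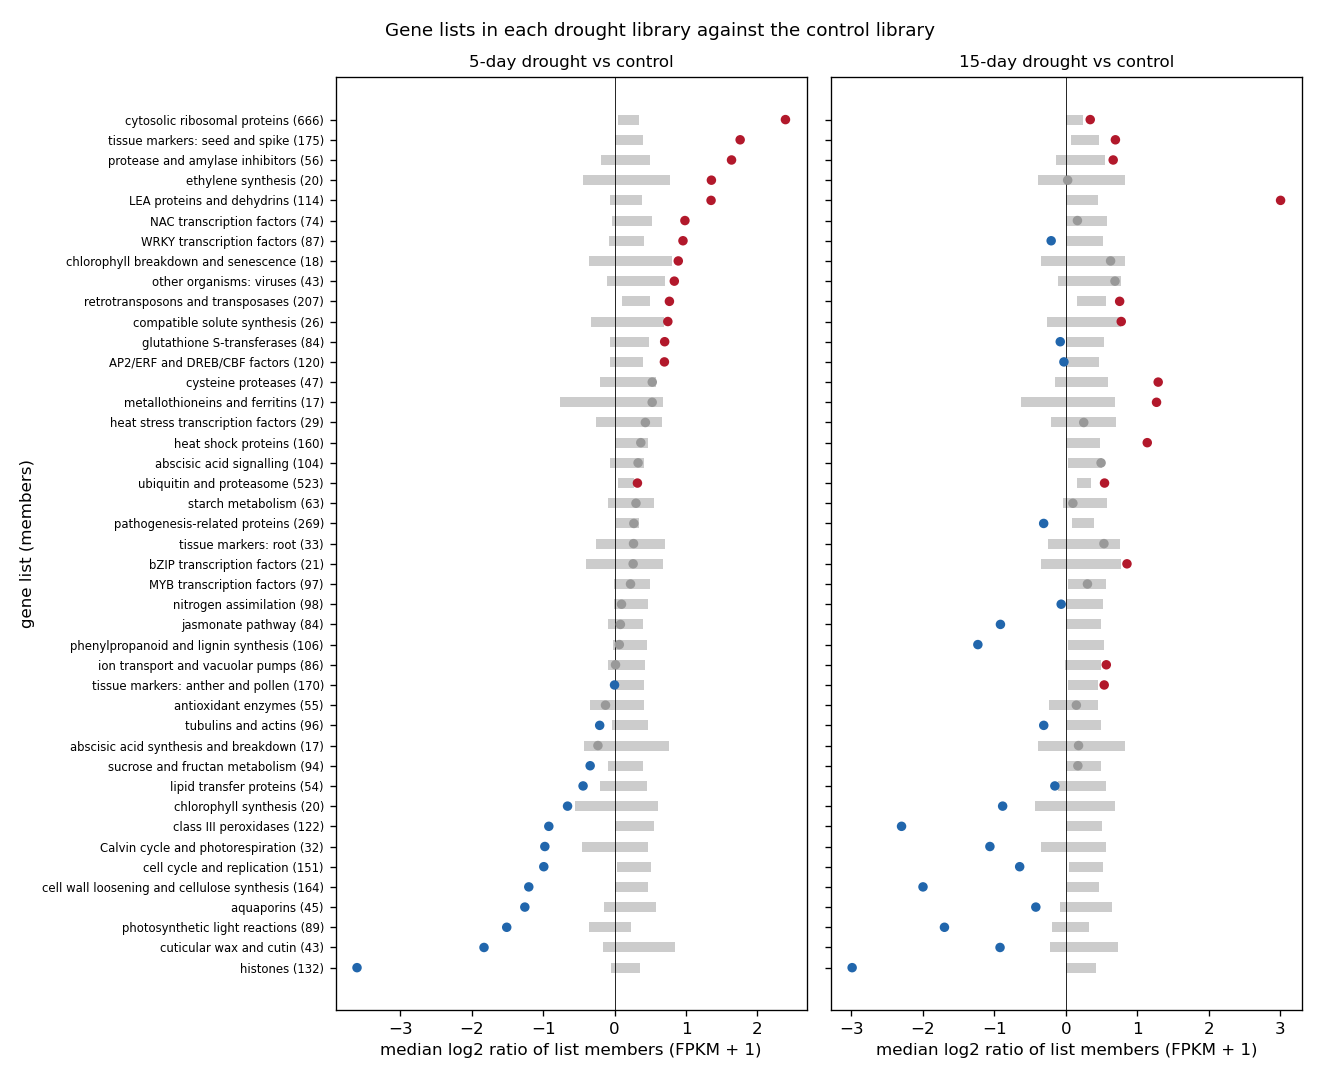
Median log2 ratio of FPKM plus 1 (x axis) of each gene list with at least 5 members (y axis, members in brackets) in the 5-day (left) and 15-day (right) library against the control. Grey bars span the middle 95% of the medians of 10000 random lists; red points lie above, blue below and grey within them, with histones lowest at 5 days (-3.61) and LEA proteins highest at 15 days (3.00).

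Cytosolic ribosomal proteins were above the random range at 5 days as a list, with 347 of 666 higher and 146 lower, but the direction depended on the first nucleotide hit. Among the 198 members with a Pooideae hit 119 were lower and 19 higher, the median log2 ratio was -1.17, and the whole list took 4.02% of control fragments and 2.14% at 5 days. Proline and branched amino acid breakdown, with 3 members, was too small for the random lists; 3 were higher at 5 days. The anther and pollen list was below the range (median log2 ratio 0.00) and within it after TMM or upper-quartile rescaling. Within the range lay cysteine proteases, metallothioneins and ferritins, abscisic acid signalling, abscisic acid synthesis, heat shock proteins (above it after either rescaling, with 31 of 60 members without a Pooideae hit higher against 14 of 100 with one), heat stress factors, pathogenesis-related proteins, starch metabolism, bZIP and MYB factors, root markers, the jasmonate pathway, nitrogen assimilation, ion transport, antioxidant enzymes and phenylpropanoid synthesis. In all, 8817 of 29478 transcripts were at least 2-fold higher at 5 days and 5259 lower, a 62.6% share of higher calls. The tested transcripts had a median log2 ratio of 0.353. TMM rescaling, with factors that shift ratios by -0.392 in log2 before the pseudocount, moved this median to -0.002. It gave 6442 higher and 8415 lower, so which direction prevailed depended on the scaling. With a Pooideae hit 4817 were higher and 4263 lower (53.1% higher), and with a minimum of 20 FPKM 2065 and 2028 (50.5%). Of the 27 lists outside the range, 15 stayed outside on their side under every alternative run; apart from those named above, a minimum of 20 FPKM ended the calls of ethylene synthesis, glutathione S-transferases, chlorophyll synthesis, chlorophyll breakdown, wax and cutin, and retrotransposons. Sums over shared descriptions ended those of sucrose and fructan, lipid transfer proteins and tubulins and actins.

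After 15 days, the lists of LEA proteins, heat shock proteins, cysteine proteases and metallothioneins lay above the random range against the control library, and those of photosynthesis, cell wall, lignin, jasmonate and histone genes below it. Of 114 LEA and dehydrin transcripts 77 were higher and 5 lower, with a median log2 ratio of 3.00. Dehydrin DHN4 stood at 0.810 FPKM in the control and 3048 at 15 days, 3764-fold higher [2318 to 6586]. Dehydrin DHN1 (CL5395.Contig1_All) had no control fragment and was at least 429-fold higher, and the LEA protein PHV A1 (CL1381.Contig9_All) was 569-fold higher [379 to 897]. A glycine-rich cell wall protein (Unigene4510_All) was 1450-fold higher [830 to 2806] and a defensin-like protein (Unigene2826_All) 502-fold higher [309 to 879]. Heat shock proteins were higher in 71 of 160 members and lower in 11 (47 and 22 after TMM rescaling), but took 0.488% of control fragments and 0.461% at 15 days; a 16.9 kDa class I protein (Unigene49238_All), with no control fragment, was at least 620-fold higher. In compatible solute synthesis, above the range but within it under 4 of 11 alternatives, upper-quartile rescaling among them, the proline-forming enzyme pyrroline-5-carboxylate synthase (CL948.Contig6_All) was 22.4-fold higher [20.8 to 24.2]. Cysteine proteases were higher in 23 of 47 members and lower in 4 (11 and 4 after TMM rescaling); a vacuolar processing enzyme (CL1438.Contig3_All) stood at 1.20 FPKM in the control and 43.7 at 15 days, and ananain (Unigene4632_All) was 121-fold lower [80.2 to 190.5]. Metallothioneins and ferritins were higher in 8 of 17 and lower in 2, and a metallothionein 2A (CL5876.Contig2_All) was 113-fold higher [96.6 to 132]. Peroxiredoxin PER1 (Unigene6419_All) was 86.4-fold higher [69.4 to 109], while the antioxidant list lay within the range. In abscisic acid signalling, also within it, a protein phosphatase 2C (Unigene5606_All) was 56.4-fold higher [36.4 to 92.8] and the abscisic acid receptor PYL4 (CL9090.Contig2_All) 20.1-fold lower [12.4 to 34.9]. The highest level after that of Rubisco was that of a ribonuclease (Unigene591_All), at 2741 FPKM in the control, 1153 at 5 days and 5556 at 15 days.

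The lists below the range at 15 days included those below it at 5 days except sucrose and fructan and the anther and pollen markers. Light-reaction transcripts were lower in 66 of 89 members and higher in 5, and a chlorophyll a-b binding protein (Unigene14546_All) was 202-fold lower [133 to 322]. The Rubisco small chain named for 5 days was 13.2-fold lower [12.9 to 13.6]. Lower and higher members numbered 17 and 0 of 32 for the Calvin cycle, 9 and 2 of 20 for chlorophyll synthesis, 15 and 6 of 45 for aquaporins, 64 and 19 of 151 for the cell cycle, 21 and 10 of 43 for wax and cutin, and 19 and 10 of 54 for lipid transfer proteins. For tubulins and actins these were 41 and 17 of 96, with 41 and 6 among the 67 with a Pooideae hit and 0 and 11 among the 29 others. Aquaporin PIP2-7 (Unigene24982_All) was 43.9-fold lower [25.4 to 82.8], and ECERIFERUM 1 (CL94.Contig2_All), a wax synthesis protein, 12.7-fold higher [9.13 to 18.0]. A germin-like protein (CL2990.Contig3_All) stood at 1318 FPKM in the control and 4.28 at 15 days, 308-fold lower [248 to 387]. Cell wall genes were lower in 112 of 164 and higher in 17. Histones were lower in 84 of 132 and higher in 20, with 69 and 3 among the 79 with a Pooideae hit and 15 and 17 among the 53 others, and histone H2A (Unigene59716_All) was 290-fold lower [133 to 792]. Class III peroxidases were lower in 70 of 122 and higher in 7, and phenylpropanoid and lignin genes lower in 54 of 106 and higher in 4; cinnamoyl-CoA reductase (CL795.Contig2_All) was 216-fold lower [109 to 501]. The jasmonate pathway was lower in 37 of 84 members and higher in 6, and nitrogen assimilation lower in 27 of 98 and higher in 19 (44 and 8 after TMM rescaling). Pathogenesis-related proteins were lower in 85 of 269 and higher in 55, while as a whole they took 1.24% of control fragments and 1.78% at 15 days. WRKY factors were below the range, with 8 of 87 higher and 14 lower (1 and 37 after TMM rescaling). WRKY 70 (Unigene9354_All) was 6.64-fold lower [5.16 to 8.65]. AP2/ERF factors were below it with 30 of 120 higher and 19 lower, a balance that TMM rescaling turned to 14 and 40, and the call ended under 6 of 11 alternatives, both rescalings among them. Of their 90 members with a Pooideae hit 25 were higher and 12 lower, and these lay within the range. Glutathione S-transferases (19 of 84 higher, 21 lower, and 9 and 32 after TMM rescaling) were also below it, but within it after TMM rescaling, with a minimum of 20 FPKM and when summed over descriptions.

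Also above the range at 15 days were protease inhibitors (20 of 56 higher, 8 lower, and 15 and 9 after TMM rescaling) and seed and spike markers (56 of 175 higher, 7 lower, and 30 and 13 after TMM rescaling). So were bZIP factors (8 of 21 higher, 1 lower) and retrotransposons (71 of 207 higher, 10 lower), although after TMM rescaling more of their members were lower than higher, 5 against 3 and 20 against 17. After upper-quartile rescaling 4 bZIP factors were higher and 4 lower, and 37 and 15 retrotransposons. Ion transport and vacuolar pumps and ubiquitin and proteasome were above the range with median log2 ratios of 0.57 and 0.54. These turned negative after TMM rescaling (-0.04 and -0.12) but not after upper-quartile rescaling (0.15 and 0.13), and the lists stayed above the range. Anther and pollen markers were higher in 61 of 170 members and lower in 35, with a median log2 ratio of 0.54. They lay within the range after either rescaling, with medians of -0.20 (TMM) and 0.02 (upper quartile). Their summed level was 10176 FPKM in the control and 4301 at 15 days. With the stricter E-value 38 members remained, which had a median log2 ratio of 1.85 and lay above the range. Ribosomal proteins were above the range as a list (median log2 ratio 0.34, and 0.13 with 86 higher and 182 lower after TMM rescaling), but 73 of the 198 members with a Pooideae hit were lower and 10 higher, and the list took 2.30% of fragments at 15 days. Within the range lay abscisic acid signalling and synthesis, chlorophyll breakdown, root markers, MYB, NAC and heat stress factors, sucrose and fructan, ethylene synthesis and starch. Of 30493 transcripts 9486 were at least 2-fold higher and 5160 lower, a 64.8% share of higher calls, with a median log2 ratio of 0.495. With a Pooideae hit 5775 were higher and 4044 lower, and with a minimum of 20 FPKM 2013 and 1833 (52.3%). TMM rescaling, with a shift of -0.665 before the pseudocount, gave a median log2 ratio of -0.104 with 3543 higher and 9641 lower. Of the 31 lists outside the range, 16 stayed outside on their side under every alternative run; apart from those named above, a minimum of 20 FPKM ended the calls of WRKY factors, wax and cutin, lipid transfer proteins, ion transport, nitrogen assimilation and retrotransposons. Sums over shared descriptions ended those of lipid transfer proteins, pathogenesis-related proteins, metallothioneins and tubulins and actins, and a stricter E-value those of protease inhibitors, ion transport and metallothioneins.

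**Figure D2:**
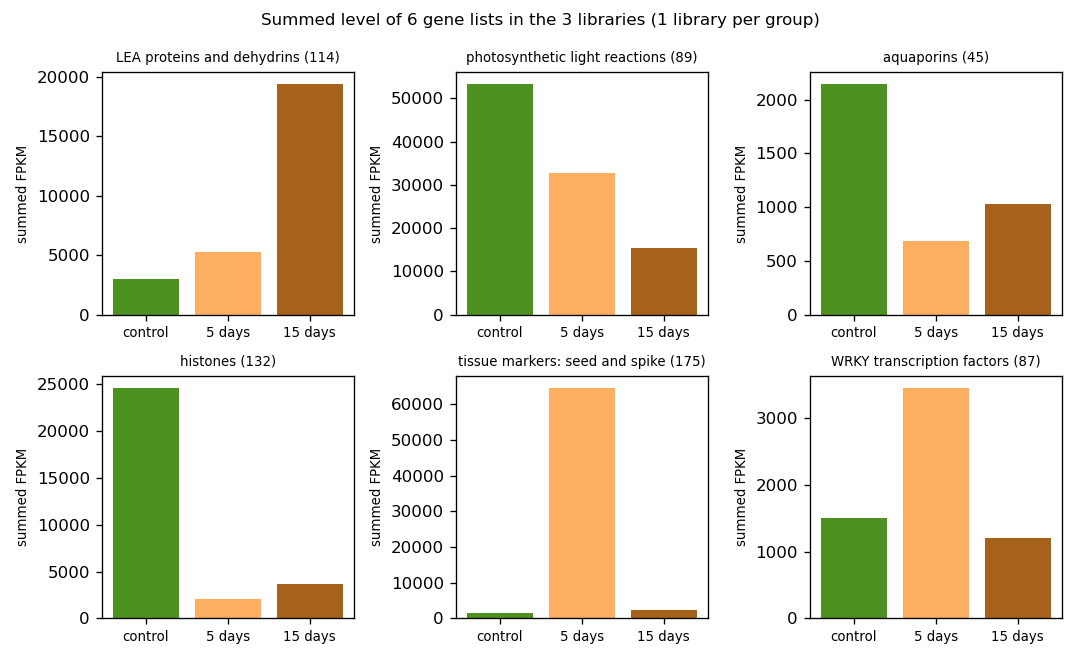
Summed FPKM (y axis, from 0) of the members of 6 gene lists in the control, 5-day and 15-day libraries (x axis), 1 library per bar and without error bars. LEA proteins sum to 3014, 5253 and 19387 FPKM, and seed and spike markers to 1602, 64674 and 2357.

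Between the drought libraries, 6124 of 33279 transcripts were at least 2-fold higher at 15 than at 5 days and 7358 lower. After TMM rescaling, with a shift of -0.273 before the pseudocount, these were 3235 and 8137. LEA proteins were higher at 15 days in 72 of 114 members and lower in 16, and heat shock proteins higher in 65 of 160 and lower in 33 (47 and 35 after TMM rescaling); of the 60 without a Pooideae hit 25 were higher and 26 lower, and the list lay within the range when summed over descriptions. Aquaporins (19 of 45 higher, 8 lower), metallothioneins (9 of 17, 4), antioxidant enzymes (19 of 55, 9) and anther and pollen markers (49 of 170, 23) were also above the range. With the stricter E-value, however, metallothioneins lay below the range, with a median log2 ratio of -0.67. Histones (28 of 132 higher, 24 lower), cysteine proteases (17 of 47, 13) and ion transport (16 of 86, 13) were above the range too, but after TMM rescaling more of their members were lower than higher. After upper-quartile rescaling, higher and lower members numbered, in that order, 24 and 23, 15 and 8, and 15 and 11, so this turn depended on the scaling. When summed over descriptions, all 3 lay within the range. With a minimum of 1 FPKM, cysteine proteases lay below it (percentile 0.04) and ion transport within it (36.3). In these 3 lists and the antioxidant enzymes, members without a Pooideae hit were more often lower than higher, as with 8 of 10 cysteine proteases and 23 of 53 histones. Anther and pollen markers summed to 6305 FPKM at 5 days and 4301 at 15 days. WRKY factors were lower in 47 of 87 and higher in 2, with a median log2 ratio of -1.23, ethylene synthesis in 10 of 20 and higher in 2, NAC factors in 27 of 74 and 5, and AP2/ERF factors in 49 of 120 and 23. The jasmonate pathway (38 of 84 lower, 10 higher), phenylpropanoid synthesis (50 of 106, 7), class III peroxidases (44 of 122, 12) and pathogenesis-related proteins (100 of 269, 53) were below the range too. Also below it were light reactions, cell wall genes, tubulins and actins, glutathione S-transferases, nitrogen assimilation, chlorophyll breakdown, and seed and spike markers (85 of 175 lower, 20 higher). The sucrose and fructan list was below it by its median log2 ratio of -0.06, although 37 of 94 members were higher and 23 lower and the summed level was 2397 FPKM at 5 days and 4105 at 15 days. Ribosomal proteins were below it (332 of 666 lower, 108 higher) and, with a Pooideae hit only, within it. Retrotransposons were below it but within it after either rescaling, and protease inhibitors were below it but within it after TMM rescaling. A lipid transfer protein (CL2120.Contig2_All) was 274-fold higher at 15 days [181 to 437]. Of the 28 lists outside the range, 9 stayed outside on their side under every alternative run: LEA proteins, jasmonate, aquaporins, light reactions, WRKY and AP2/ERF factors, cell wall genes, phenylpropanoid synthesis, and seed and spike markers. The lowest ratios were those of storage proteins, among them B1-hordein (Unigene30133_All), at 851 FPKM at 5 days and 0.205 at 15 days, 4149-fold lower [744 to 163965].

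Against the shared control, 2059 transcripts were higher in both drought libraries, 3506 lower in both, 250 higher at 5 and lower at 15 days, and 64 the reverse, among 23257 that reached 5 FPKM in the higher library of each comparison. Independent lists of these sizes would share 678.7 and 1166.8, and 20 simulated sets of unchanged libraries, with counting error only, gave means of 1.4 and 1.85. This level filter depends on the differences themselves, since a transcript that is low in the control and high in 1 drought library is left out, and 3653 of the 8817 higher at 5 days remain. With the level taken from the highest of the 3 libraries, 3574 were higher in both, against 2669.4 for independent lists, and 3506 lower, against 817.7. With the level taken from the control, these were 604 against 197.0 and 3506 against 1385.9. Simulated means for higher in both were 3.05 and 0.0. How far the higher lists exceed independent ones therefore depended on the filter. The single control library could not be split, and the simulation did not vary it beyond counting error. Part of the excess may therefore come from the control library.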

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

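The test on other pollen-abundant families was written before its values were seen; the restriction to Pooideae hits and the upper quartile for lists were chosen after seeing the data. Differences between the drought libraries were not tested, since each is a single library.

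Some lists lay on opposite sides of the random range in the drought libraries when each was set against the control. WRKY factors were above it at 5 days and below it at 15 days, and their median log2 ratio of the 15-day to the 5-day library was -1.23. The WRKY call at 15 days ended with a minimum of 20 FPKM (percentile 3.33). AP2/ERF and DREB factors did the same with -0.38, but their call at 15 days ended under 6 of 11 alternatives, both rescalings among them; the 90 members with a Pooideae hit had a median log2 ratio of 0.22 at 15 days and the 30 others -0.59. Glutathione S-transferases did so with -0.40, but at 15 days lay within the range after TMM rescaling, with a minimum of 20 FPKM and when summed over descriptions, and at 5 days with a minimum of 20 FPKM. Anther and pollen markers went from below to above with 0.43, but were within the range against the control after TMM or upper-quartile rescaling, and their summed level was 10176 FPKM in the control, 6305 at 5 days and 4301 at 15 days. With the stricter E-value 38 of the 170 members remained. These had a median log2 ratio to the control of -0.06 at 5 days, within the range, and 1.85 at 15 days, above it.

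Of 16 pollen allergen transcripts, 13 were at least 4-fold higher in the 15-day library than in both others. This group was chosen after its values were seen, and all 16 were in a list fixed earlier. Only 2 of the 16 reached 5 FPKM in the control. Members that passed the minimum level only through a drought library have a high ratio by construction. Phl p 1 (Unigene49026_All) had 1 fragment in the control, 1 at 5 days and 890 at 15 days. No technical explanation was tested for them. A candidate explanation is more pollen in the 15-day sample, which the labels say held tassel. By description, 59 transcripts were matched to other families abundant in pollen, 12 of them in a list fixed earlier. Of the 59, 11 (18.6%, exact 95% interval 9.7 to 30.9) were at least 4-fold higher than in both others, against 3.56% of all annotated transcripts. This interval treats transcripts as independent draws, although several can be copies of the same gene. The same families had a median log2 ratio to the control of -1.22 and 37 members reached 5 FPKM in the control, and 9 were at least 4-fold higher in the control than in both others. The matches also took in polygalacturonase inhibitors, which are not polygalacturonases. The most abundant of the 59 was such an inhibitor (Unigene19534_All), at 142 FPKM in the control, 20.3 at 5 days and 31.9 at 15 days. The families are therefore no clean measure of pollen, and an effect of drought on these genes was not tested.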

How the results depend on the processing

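No paired analysis was possible because each group held 1 library. The limits to Pooideae hits and to a stricter E-value, the totals without the seed list, the upper quartile for lists and the other levels for the overlap were chosen after seeing the data. The counts of different transcripts for 5 days, 15 days and 15 against 5 days stayed within 1.5 times under both rescalings, a pseudocount of 0.1, the interval beyond 2-fold and totals without the seed list, although the rescalings turned the balance of directions at 5 and 15 days. They moved, in that order, to 8444, 7646 and 7510 with a pseudocount of 5, 29796, 32478 and 30417 without a minimum level, 4093, 3846 and 3407 with a minimum of 20, 6084, 5389 and 5717 at 4-fold, 6825, 7851 and 6691 when summed over descriptions, and 8532, 8801 and 7536 for at least 500 bases. With Pooideae hits they moved to 9080 and 7689 for 5 days and for 15 against 5 days. Fewer transcripts enter under the stricter settings; otherwise the cause was not tested. The overlap of 5565 transcripts moved to 2017 at 4-fold and 1840 with a minimum of 20. With Pooideae hits and with the level taken from the highest of the 3 libraries or from the control it stayed within 1.5 times, although with these levels 3574 and 604 were higher in both, against 2059. The number of lists outside the random range stayed within 1.5 times under every alternative run, but which lists these were did not: of 27, 31 and 28 calls, 12, 15 and 19 ended under at least 1 of the 11 alternatives, and 11, 5 and 7 lists within the range lay outside under at least 1. With the median on the same side, a minimum of 20 ended 6, 9 and 9 calls and sums over descriptions 3, 6 and 10. Lipid transfer at 5 days went to 45.7 and tubulins to 18.4 when summed, and metallothioneins at 15 days to 79.6 with the stricter E-value. Percentiles that moved across 50 with a call in the main or the other setting were as follows, and the cause was not tested. With a minimum of 20: abscisic acid synthesis at 5 days 99.87, ethylene synthesis at 15 days 99.74, chlorophyll breakdown at 5 days 28.0, ribosomal proteins 0.0 at both times, anther and pollen at 15 days 40.4, and for 15 against 5 days sucrose and fructan 60.9 and ethylene synthesis 63.4. With a minimum of 1: root markers at 5 days 0.61, and for 15 against 5 days abscisic acid signalling 1.56, cysteine proteases 0.04 and ion transport 36.3. Summed over descriptions: at 5 days jasmonate 99.34, compatible solutes 40.8, sucrose and fructan 74.3 and ribosomal proteins 0.07, and at 15 days lipid transfer 51.3 and ribosomal proteins 0.12. With Pooideae hits: ribosomal proteins 0.0 at both times and 67.6 for 15 against 5 days, and AP2/ERF at 15 days 61.4. With the stricter E-value, metallothioneins for 15 against 5 days 1.43. The jasmonate list at 5 days, above the range when summed, lay below it with the stricter E-value (0.02). Depth limits what can be said of transcripts near the level of 3 fragments, which for 1 kb is 0.157 FPKM in the control and 0.173 at 5 days.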

Other observations

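All of the tests and gene lists in this part were chosen after the first results were seen. The intervals in this part treat each transcript as an independent draw. Several transcripts can be copies of the same gene, so the intervals may be too narrow, and they do not cover spread between libraries. Lists fixed earlier already held 28 of the 36 S-phase, 84 of the 94 mitotic, 30 of the 65 other grain, 24 of the 40 oil body and globulin and 2 of the 134 translation factor transcripts, and 1 translation factor had been seen by name. They also held 6 of the 82 plastid-encoded and 86 of the 87 storage prolamin transcripts.

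The 36 transcripts of S-phase genes took 0.133% of fragments in the control, 0.0267% at 5 days and 0.0529% at 15 days, and 15 of them were at least 4-fold higher in the control than in both others. Proliferating cell nuclear antigen (Unigene28577_All) stood at 106, 11.5 and 20.9 FPKM, and the small chain of ribonucleotide reductase (Unigene18919_All) at 213, 34.8 and 65.2 FPKM. The median log2 ratio of the list was -0.84 at 5 days and -0.12 at 15 days, which is less than 2-fold lower at the median. The 94 transcripts of the mitotic list had median log2 ratios of -1.11 and -0.92. Its most abundant members included the kinesin-like protein FLA10 (Unigene24212_All) and an N-acetylglucosaminyltransferase (Unigene15262_All). Their descriptions name no mitotic role, so the list is not limited to mitosis. Transcripts were matched as plastid-encoded by description, and where each is encoded was not checked. The 64 of these with a Pooideae hit had median log2 ratios of -0.05 at 5 days and -0.40 at 15 days, against -1.51 and -1.69 in the list of light reactions. The difference was not tested.

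Storage prolamins took 0.128% of fragments in the control, 3.26% at 5 days and 0.182% at 15 days. After TMM rescaling 94 of the 175 seed and spike markers were higher at 5 days and 9 lower; no other technical explanation was tested. A candidate explanation is developing grain in the 5-day sample. Among 65 transcripts of other grain genes, the first list tried, 15 (23.1%, exact 95% interval 13.5 to 35.2) were at least 4-fold higher than in both others, against 6.1% of all annotated transcripts. Of the 35 in no list fixed earlier 10 were (28.6%, 14.6 to 46.3). The median log2 ratio of the 65 was 0.58, and 35 reached 5 FPKM in the control. The median was 0.46 in the 54 with a Pooideae hit and 2.06 in the 11 others. The most abundant members were a protein disulfide-isomerase (Unigene27786_All) and a beta-amylase (CL5147.Contig2_All). In the control, 5-day and 15-day libraries the first stood at 292, 210 and 616 FPKM, the second at 0.0664, 368 and 0.658. The list is therefore no clean measure of grain. A second list, of 40 oil body and globulin transcripts, was written after values of the first and of some of its own members were seen. Of the 40, 14 (35%, 20.6 to 51.7) were at least 4-fold higher than in both others, but of the 16 in no list fixed earlier 3 were (18.8%, 4.0 to 45.6), too few to decide. Whether drought or the stage of the tassel set this difference cannot be separated with 1 library per group, and it was not tested.

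Ribosomal protein transcripts parted by their first nucleotide hit, with median log2 ratios of -1.17 with a Pooideae hit and 2.97 without at 5 days, and -0.84 and 0.97 at 15 days. Grass copies with another regulation were examined through the first protein hit. It was a grass for 107 (32.6%, exact 95% interval 27.6 to 38.0) of the 328 transcripts without a Pooideae nucleotide hit that were higher at 5 days. It was a grass for 171 (86.4%) of the 198 chosen by a Pooideae nucleotide hit, and for 68 (48.6%) of the 140 without one and not higher. Within the 328, the median log2 ratio at 5 days was 3.35 with a grass protein hit and 3.36 in the others. The 328 were chosen as higher at 5 days, so a rise in both was fixed by that choice. The protein hit therefore does not decide whether grass copies are the cause. Of the 107, 73 had a Pooideae species as first protein hit, barley (Hordeum vulgare subsp. vulgare) for 70, so the nucleotide hit does not by itself mark the origin. Another candidate explanation is RNA of another eukaryote in the 5-day library. In translation factors, the median log2 ratio at 5 days of the 50 members without a Pooideae hit exceeded that of the 84 with one by 3.03 (bootstrap 95% interval 2.78 to 3.40). Only 66 of the 134 translation factors reached 5 FPKM in the control. Members that passed the minimum level only through a drought library have a high ratio by construction. Part of this difference may therefore come from the filter, and it does not settle the origin. At 15 days the same difference was 0.84 (0.34 to 1.43), which decides nothing for that library, and which organism this would be was not tested.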
